A study of Mus musculus with 20 samples.

How the data were processed

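The study sequenced polyadenylated RNA from livers of wild-type and STING knockout mice after 7 days of bile duct ligation or after sham surgery. Each of the 4 groups held 5 libraries. Per the labels, RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit. The deposited table holds FPKM values that the authors computed, with 1 column per library and 54532 gene entries. Per the submitters' processing notes, CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used with the builds GRCm38 and mm10, without a role or an order for each, and the annotation release is not given in the sources used here. Groups were taken from the sample titles, which are used here as library names. The titles give each library its own number and nothing else says that the livers came from separate animals, so the p-values measure the spread between these libraries. Mice lacking Abcb4, which the series design also names, were not analysed here.

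The unit was checked on the values. Multiplied by the exonic length of GENCODE M21 genes, 98.13 to 98.51% of low values in each library were whole multiples of 1 step (tolerance 0.02), which gave fragments per gene and a depth of 14.95 to 20.9 M assigned fragments per library. The sum of FPKM ranged from 315016 to 547332, and the 10 genes with most fragments held 15.86 to 23.13% of them. The deposited values were already scaled between libraries by median ratio, since that ratio was 1.0065 in all 20 libraries over 14767 genes, and assigned fragments were 86.92 to 134.3% of the scaled library size. Of the tested entries 13958 (99.3%) matched a single M21 gene, and 105 entries repeated an earlier gene name.

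Values were analysed as log2(FPKM + 0.5). Genes with at least 0.5 FPKM in at least 5 of the 20 libraries, 14059 in all, were tested with limma 3.58.1 in R 4.3.3, in 1 linear model with a mean per group and moderated variances with a trend and robust estimation. The tests were ligation against sham in each genotype, knockout against wild type after each surgery, and the interaction of both. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The level of Tmem173 was compared by exact permutation tests. A response score averaged, per library, the signed log2 values of genes called for the average ligation effect, and its interaction was tested by exact permutation of genotype within each surgery over 63504 permutations. Calls within 10 Mb of Tmem173 were compared with those elsewhere by Fisher's exact test. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used to read the files and draw figures.

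The 28 gene lists were tested with camera from limma with an inter-gene correlation of 0.01, with adjustment over the lists of 1 comparison, and again with the correlation estimated from the data. Members were counted as called over all genes and with the adjustment over the list alone. The comparisons, tests, lists, a first set of other settings and the rule for named genes were fixed before the data were examined. That rule takes Tmem173, Nnt, the 5 protein-coding genes with the largest increase and the 5 with the largest decrease per test (among called genes with a mean of at least 1 FPKM in 1 group and, in the pairwise comparisons, no overlap of the groups), and up to 4 called members of each list, or its 2 most abundant members where fewer than 2 were called. The text names a subset of these genes.

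The settings in that first set were pseudocounts of 0.1 and 1, no filter or a filter at 1 FPKM, TPM, median-ratio scaling, quantile normalization, moderation without robust estimation, array weights, only the 2 groups compared in the fit, and the removal of each library in turn. Chosen after seeing the data were scaling to total fragments, voom on recovered fragments, library type as a covariate, each library type alone, and removal of libraries BDL_KO_2248 and BDL_KO_2359. The pipeline was tested on simulated data with known changes. Of genes changed 2-fold it recovered 56.7 to 65.3% in the 4 pairwise comparisons, of genes changed 4-fold 82 to 85.3%, with 4 to 5.9% false calls, and it called a list lowered 2-fold in 3 of 3 runs for the knockout after ligation and for the interaction, with 1 of 81 tests of other lists called in each. For the knockout after sham surgery, where no change was planted, it called that list in 0 of 3 runs and the other lists in 0 of 81 tests. Simulated genes were drawn independently, with 1 spread per gene for all groups. These runs therefore do not test camera on correlated members, and the estimated correlation of the type I interferon-stimulated list was 0.687. Nor do they test a group that varies more than the others.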

Results

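Polyadenylated liver RNA was sequenced in 20 libraries, in 4 groups of 5, namely sham-operated wild type, sham-operated STING knockout, bile duct-ligated wild type and bile duct-ligated STING knockout. Bile duct ligation blocks the outflow of bile and causes cholestasis, and it had lasted 7 days here. STING is the adaptor that relays the sensing of cytosolic DNA by cGAS to type I interferon genes, and the series asks what its loss does to gene expression in cholestatic liver. The libraries held 14.95 to 20.9 M fragments assigned to genes. At that depth, 1 fragment on a transcript of 1 kilobase was worth about 0.05 to 0.07 FPKM, so values well under 0.5 FPKM rest on few fragments. Fold changes below are differences of mean log2(FPKM + 0.5) ± standard error from limma with n = 5 livers per group, and this scale understates changes of low genes. Group levels are mean FPKM ± SD.

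Tmem173, the gene of STING (ENSMUSG00000024349, chromosome 18, 35733679 to 35740554 on the minus strand of GRCm38), was lower in both knockout groups. It measured 1.71 ± 0.544 FPKM in sham wild-type and 0.743 ± 0.189 in sham knockout livers (n = 5 each), a difference of -0.80 log2 units (exact permutation p = 0.0159, two-sided). After ligation it measured 3.64 ± 0.861 FPKM in wild-type and 1.42 ± 0.762 in knockout livers, a difference of -1.17 log2 units (exact permutation p = 0.00794, the smallest that 5 against 5 can give). All 5 ligated knockout libraries lay below the 5 ligated wild-type libraries, but knockout library BDL_KO_2370, at 2.57 FPKM, reached nearly the lowest wild-type value of 2.60. In the sham groups the wild-type library Sham_Wt_2224, at 0.843 FPKM, lay below the highest knockout value of 1.06. The deleted part of the gene is not given in the sources used here, so transcript left in the knockout libraries checks their labels only in part. Nnt, which is partly deleted in the C57BL/6J substrain, lay between 0.0157 and 0.171 FPKM in the 20 libraries.

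**Figure D1:**
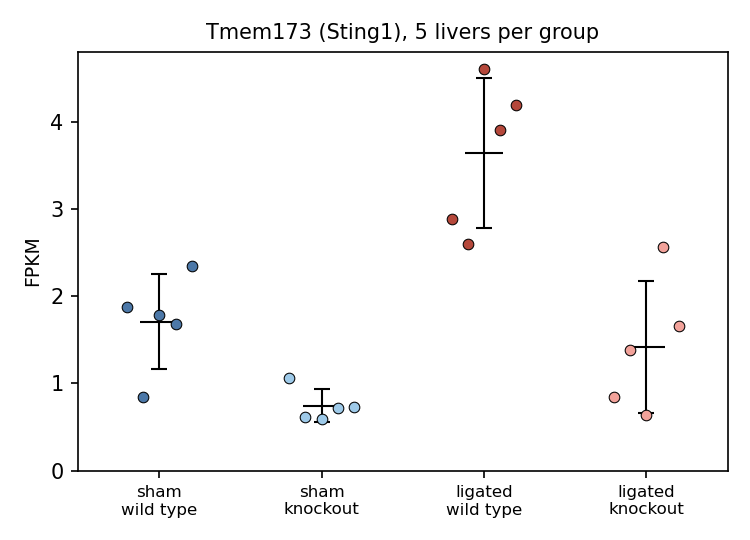
Tmem173 level in FPKM (vertical axis) in the 4 groups (horizontal axis). Each point is 1 liver library, bars are the mean and 1 SD of 5 libraries, and knockout means are 0.743 after sham surgery and 1.42 after ligation against 1.71 and 3.64 in wild type.

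Along the first principal component of the 14059 tested genes, which held 41.0% of the variance, ligated wild-type libraries lay on one side and sham libraries on the other. The 5 ligated knockout libraries lay between them, BDL_KO_2359 at -0.403, BDL_KO_2248 at 10.6, BDL_KO_2371 at 15.9, BDL_KO_2365 at 30.6 and BDL_KO_2370 at 42.0. Libraries BDL_KO_2359 and BDL_KO_2248 were the lowest of all on the second component, at -31.7 and -67.6. Their median correlations with the other libraries of their group were 0.948 and 0.919, against a median of 0.964 for pairs within groups. In BDL_KO_2365, BDL_KO_2370 and BDL_KO_2371 this value was 0.957, 0.954 and 0.958, so by this measure BDL_KO_2359 lay close to its group. Markers of 6 cell populations other than hepatocytes, among them cholangiocytes, stellate cells, monocytes and Kupffer cells, were lower in BDL_KO_2359 and BDL_KO_2248 than in the other 3 ligated knockout libraries, while their hepatocyte genes were higher. For the lists reported below that involve the ligated knockout group, the number of called members is therefore also given without them, a choice made after seeing the data. Y-linked transcripts marked 10 libraries, 2, 3, 3 and 2 in sham wild-type, sham knockout, ligated wild-type and ligated knockout livers, and Xist, which is transcribed from the inactive X chromosome, marked the other 10.

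**Figure D2:**
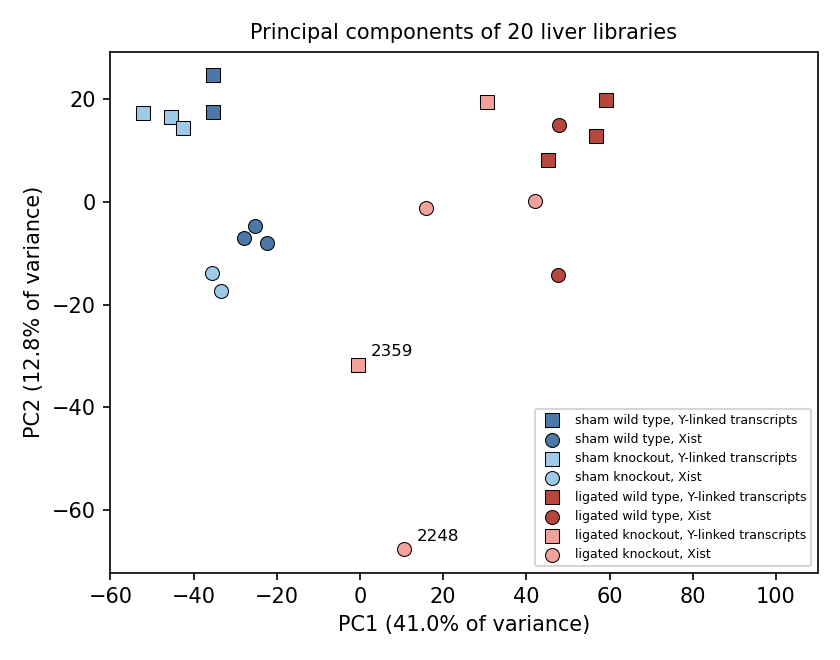
Principal components 1 and 2 (horizontal and vertical axes, in units of the component score) of log2(FPKM + 0.5) for 14059 genes. Each point is 1 of 20 liver libraries, colour marks the group, squares carry Y-linked transcripts, circles carry Xist, and ligated knockout libraries BDL_KO_2359 and BDL_KO_2248 are labelled.

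The first comparison asks how wild-type liver responds to ligation. Of 20 acute phase genes 13 rose, of 12 cholangiocyte markers 11 and of 27 stellate cell and matrix genes 15, while 12 of 19 hepatocyte genes fell, and camera called none of these lists with an estimated correlation. Lcn2, an iron-scavenging acute phase protein, rose by 7.18 ± 0.63 log2 units, from 11.1 ± 13.0 to 992 ± 217 FPKM (limma adjusted p = 3.13e-07), and the acute phase genes Orm2 and Saa2 rose by 5.57 ± 0.56 and 5.46 ± 0.83. Spp1, which encodes osteopontin, rose by 4.15 ± 0.47, Krt19, a keratin of bile duct cells, by 2.34 ± 0.29, Timp1, an inhibitor of metalloproteinases, by 4.31 ± 0.37 and Col1a1, a fibrillar collagen, by 3.13 ± 0.56. Sult2a8, a hepatic sulfotransferase, fell by 6.20 ± 0.52, from 237 ± 73.4 to 3.89 ± 4.75 FPKM. The major urinary protein genes Mup12, Mup17 and Mup16 fell by 8.91 ± 1.55, 7.95 ± 1.14 and 7.08 ± 0.90, but these paralogs share reads, so their single values are uncertain, and voom on recovered fragments did not call Mup12 or Mup17. Of 14059 genes tested, 5011 changed, 2544 higher and 2467 lower, 1358 of them by at least 2-fold. Genes called higher made up 50.8% as deposited, 71.2% after scaling to total fragments, which moved the median gene by 0.16 log2 units, and 82.8% as TPM, which moved it by 0.29. With only the libraries carrying Y-linked transcripts 3126 genes changed, and with only those carrying Xist 911.

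Of 12 measured genes of bile acid synthesis, 6 fell with ligation in wild type, and 6 adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.381 with an estimated correlation). Among them Cyp8b1, which directs synthesis to cholic acid, fell by 2.49 ± 0.49. Of 13 bile acid and lipid transporters, 5 fell and 2 rose, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.194). The uptake carriers Slco1a1 and Slc10a1 fell by 4.38 ± 0.55 and 2.00 ± 0.36, and Slc51b, part of a basolateral efflux carrier, rose by 2.81 ± 0.31. Of 10 bile acid receptors and signalling genes, 1 rose and 2 fell, the same counts adjusted over the list alone (camera adjusted p = 0.527).

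Of 12 cholangiocyte markers 11 rose with ligation in wild type, 11 adjusted over the list alone, including the tight junction gene Cldn4 by 2.79 ± 0.38 (camera adjusted p = 3.44e-08, and adjusted p = 0.25 with an estimated correlation). Of 27 stellate cell and matrix genes 15 rose, 15 adjusted over the list alone, with the collagen Col3a1 up by 2.32 ± 0.64 (camera adjusted p = 1.82e-05, and adjusted p = 0.381 with an estimated correlation). Of 17 monocyte and recruited macrophage markers 13 rose, 15 adjusted over the list alone, with the chemokine receptor Ccr2 up by 2.43 ± 0.31 and Gpnmb, a gene of lipid-laden macrophages, by 2.58 ± 0.27 (camera adjusted p = 7.39e-08). All 5 measured neutrophil markers rose, also adjusted over the list alone (camera adjusted p = 0.00127), and for both of these lists adjusted p = 0.25 with an estimated correlation. Of 9 Kupffer cell markers 3 rose, 3 adjusted over the list alone (camera adjusted p = 0.0178, and adjusted p = 0.381 with an estimated correlation). Of 12 sinusoidal endothelial markers 9 fell, 9 adjusted over the list alone, with the secreted DNase gene Dnase1l3 down by 1.60 ± 0.25 (the log2 fold change was -1.60). Of 19 hepatocyte genes 12 fell, 12 adjusted over the list alone, among them the transthyretin gene Ttr, which fell by 2.03 ± 0.25. Camera gave adjusted p = 0.000262 and 7.53e-06 for these 2 lists, and adjusted p = 0.307 with an estimated correlation for both. None of 6 T and NK cell markers passed (camera adjusted p = 0.966), with a median of opposite sign to the mean and the test, 1 of 6 B and plasma cell markers fell (camera adjusted p = 0.384), and none of 6 blood, pancreas and fat markers passed (camera adjusted p = 0.816). Adjusted over the list alone, those 3 counts were 0, 1 and 0.

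Of 34 type I interferon-stimulated genes 27 rose with ligation in wild type, and adjusted over the list alone 28 rose and 1 fell (camera adjusted p = 2.4e-08, and adjusted p = 0.33 with an estimated correlation). The antiviral effectors Rsad2 and Mx1 rose by 2.20 ± 0.49 and 2.15 ± 0.29. Of 20 cytokine, chemokine and NF-kB target genes 16 rose, 17 adjusted over the list alone, with the neutrophil chemokine gene Cxcl1 up by 3.39 ± 0.56 and the NF-kB feedback gene Tnfaip3 by 2.88 ± 0.26 (camera adjusted p = 3.48e-08, and adjusted p = 0.25 with an estimated correlation). Of 20 acute phase genes 13 rose, 13 adjusted over the list alone (camera adjusted p = 8.92e-07, and adjusted p = 0.289 with an estimated correlation). Of 20 cell death genes 10 rose, 12 adjusted over the list alone, including the cell cycle inhibitor Cdkn1a by 3.17 ± 0.44 (camera adjusted p = 3.18e-05, and adjusted p = 0.25 with an estimated correlation). Of 11 cGAS-STING pathway genes 7 rose and 2 fell, the same counts adjusted over the list alone (camera adjusted p = 0.0301, and adjusted p = 0.313 with an estimated correlation), and without BDL_Wt_2240 camera gave adjusted p = 0.0527. Of 23 interferon gamma and antigen presentation genes 4 rose and 2 fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.0835).

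Among metabolic lists, 15 of 20 fatty acid oxidation and PPARalpha target genes fell, 15 adjusted over the list alone, with the omega-hydroxylase gene Cyp4a10 down by 2.66 log2 units (log2 fold change -2.66 ± 0.58). Of 22 drug metabolism enzymes 12 fell and 2 rose, the same counts adjusted over the list alone, and Cyp2c37 fell by 3.51 ± 0.51. Camera gave adjusted p = 1.83e-07 and 6.12e-05 for these lists, and adjusted p = 0.25 with an estimated correlation for both. Of 20 cholesterol synthesis and SREBP2 target genes 10 rose and 1 fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.00167, and adjusted p = 0.431 with an estimated correlation). Of 16 oxidative stress and NRF2 target genes 8 rose, and adjusted over the list alone 9 rose and 1 fell (camera adjusted p = 0.00616, and adjusted p = 0.25 with an estimated correlation). Camera did not call lipogenesis and lipid droplet genes (7 of 19 fell and 1 rose, adjusted p = 0.0608), unfolded protein response genes (4 of 20 rose, adjusted p = 0.113), cell cycle genes (1 of 22 rose, adjusted p = 0.293), clock genes (1 of 15 rose and 2 fell, adjusted p = 0.726) or sex-biased genes (1 of 17 fell, adjusted p = 0.198). Adjusted over the list alone, 7 fell and 1 rose, 4 rose, 0 changed, 1 rose and 1 fell, and 1 fell in these lists.

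The next comparison gives the response of knockout liver to ligation. Of 20 acute phase genes 13 rose and 1 fell, of 20 cholesterol synthesis genes 18 rose and of 20 fatty acid oxidation genes 18 fell, and camera called none of these lists with an estimated correlation. Lcn2 rose by 6.99 ± 0.63, from 3.25 ± 1.98 to 487 ± 299 FPKM (limma adjusted p = 9.49e-07), and Orm2 rose by 5.51 ± 0.56. Saa2 rose by 6.17 ± 0.83, with a mean of 1552 ± 2944 FPKM after ligation because library BDL_KO_2248 reached 6813. Fasn, the fatty acid synthase gene, rose by 1.81 ± 0.20, its activator Srebf1 by 1.45 ± 0.29, and the cholesterol synthesis gene Fdps by 2.20 ± 0.44, or by 1.29 without libraries BDL_KO_2359 and BDL_KO_2248. Acot1, an acyl-CoA thioesterase gene, fell by 4.29 ± 0.40, and Cyp4a10 fell by 4.21 ± 0.58. Of the genes tested 3534 changed, 1725 higher and 1809 lower, 735 of them by at least 2-fold. Genes called higher made up 48.8% as deposited, 57.8% after scaling to total fragments (median shift 0.05) and 77.0% as TPM (median shift 0.17). The count was 1072 in libraries with Y-linked transcripts, 550 in those with Xist and 1694 with only these groups in the fit, and without libraries BDL_KO_2359 and BDL_KO_2248 it was 5199, of which 3058 were shared.

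By list, 18 of 20 cholesterol synthesis genes rose in the ligated knockout, 19 adjusted over the list alone, and 18 rose without libraries BDL_KO_2359 and BDL_KO_2248 (camera adjusted p = 1.27e-14, and adjusted p = 0.201 with an estimated correlation). Of 20 fatty acid oxidation genes 18 fell, 18 adjusted over the list alone and 18 without the 2 libraries (camera adjusted p = 1.27e-14, and adjusted p = 0.171 with an estimated correlation). Of 20 acute phase genes 13 rose and 1 fell, or 14 and 1 adjusted over the list alone and 11 and 1 without the 2 libraries, with the list median going from 1.69 to 1.18 (camera adjusted p = 9.17e-09, and adjusted p = 0.314 with an estimated correlation). Of 12 cholangiocyte markers 8 rose, 10 adjusted over the list alone, with Spp1 up by 2.93 ± 0.47 and Krt19 by 1.71 ± 0.29, and 9 rose without the 2 libraries, with the list median going from 1.022 to 1.603 (camera adjusted p = 2.19e-05, and adjusted p = 0.361 with an estimated correlation). Of 20 cytokine and NF-kB target genes 10 rose, 10 adjusted over the list alone, with Cxcl1 up by 3.69 ± 0.56, and 15 rose without the 2 libraries, with the list median going from 0.627 to 1.101 (camera adjusted p = 1.34e-05, and adjusted p = 0.361 with an estimated correlation). Of 17 monocyte markers 8 rose, 9 adjusted over the list alone, and 14 rose without the 2 libraries (camera adjusted p = 8.48e-05, and adjusted p = 0.459 with an estimated correlation). Trem2, a receptor of lipid-associated macrophages, rose by 1.33 ± 0.23. Of 27 stellate cell and matrix genes 9 rose, 9 adjusted over the list alone, with Timp1 up by 3.04 ± 0.37, and 21 rose without the 2 libraries (camera adjusted p = 0.000324, and adjusted p = 0.584 with an estimated correlation).

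None of the 34 type I interferon-stimulated genes rose with ligation in knockout liver, and 2 fell, or 1 adjusted over the list alone (camera adjusted p = 0.608). Irf9, a subunit of the interferon-activated transcription factor ISGF3, fell by 0.74 ± 0.11. Without libraries BDL_KO_2359 and BDL_KO_2248, 8 rose and 1 fell. Of 19 lipogenesis and lipid droplet genes 7 rose and 4 fell, also adjusted over the list alone, and without the 2 libraries 8 rose and 3 fell (camera adjusted p = 0.161). Across the 14059 genes the responses of the 2 genotypes, which share no library, had a Pearson correlation of 0.786 and a Spearman correlation of 0.717, and genes are not independent replicates. Among genes called in both, 1248 were higher in both, 1268 lower in both and 11 opposite, where independent lists would share 312 and 317.

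**Figure D3:**
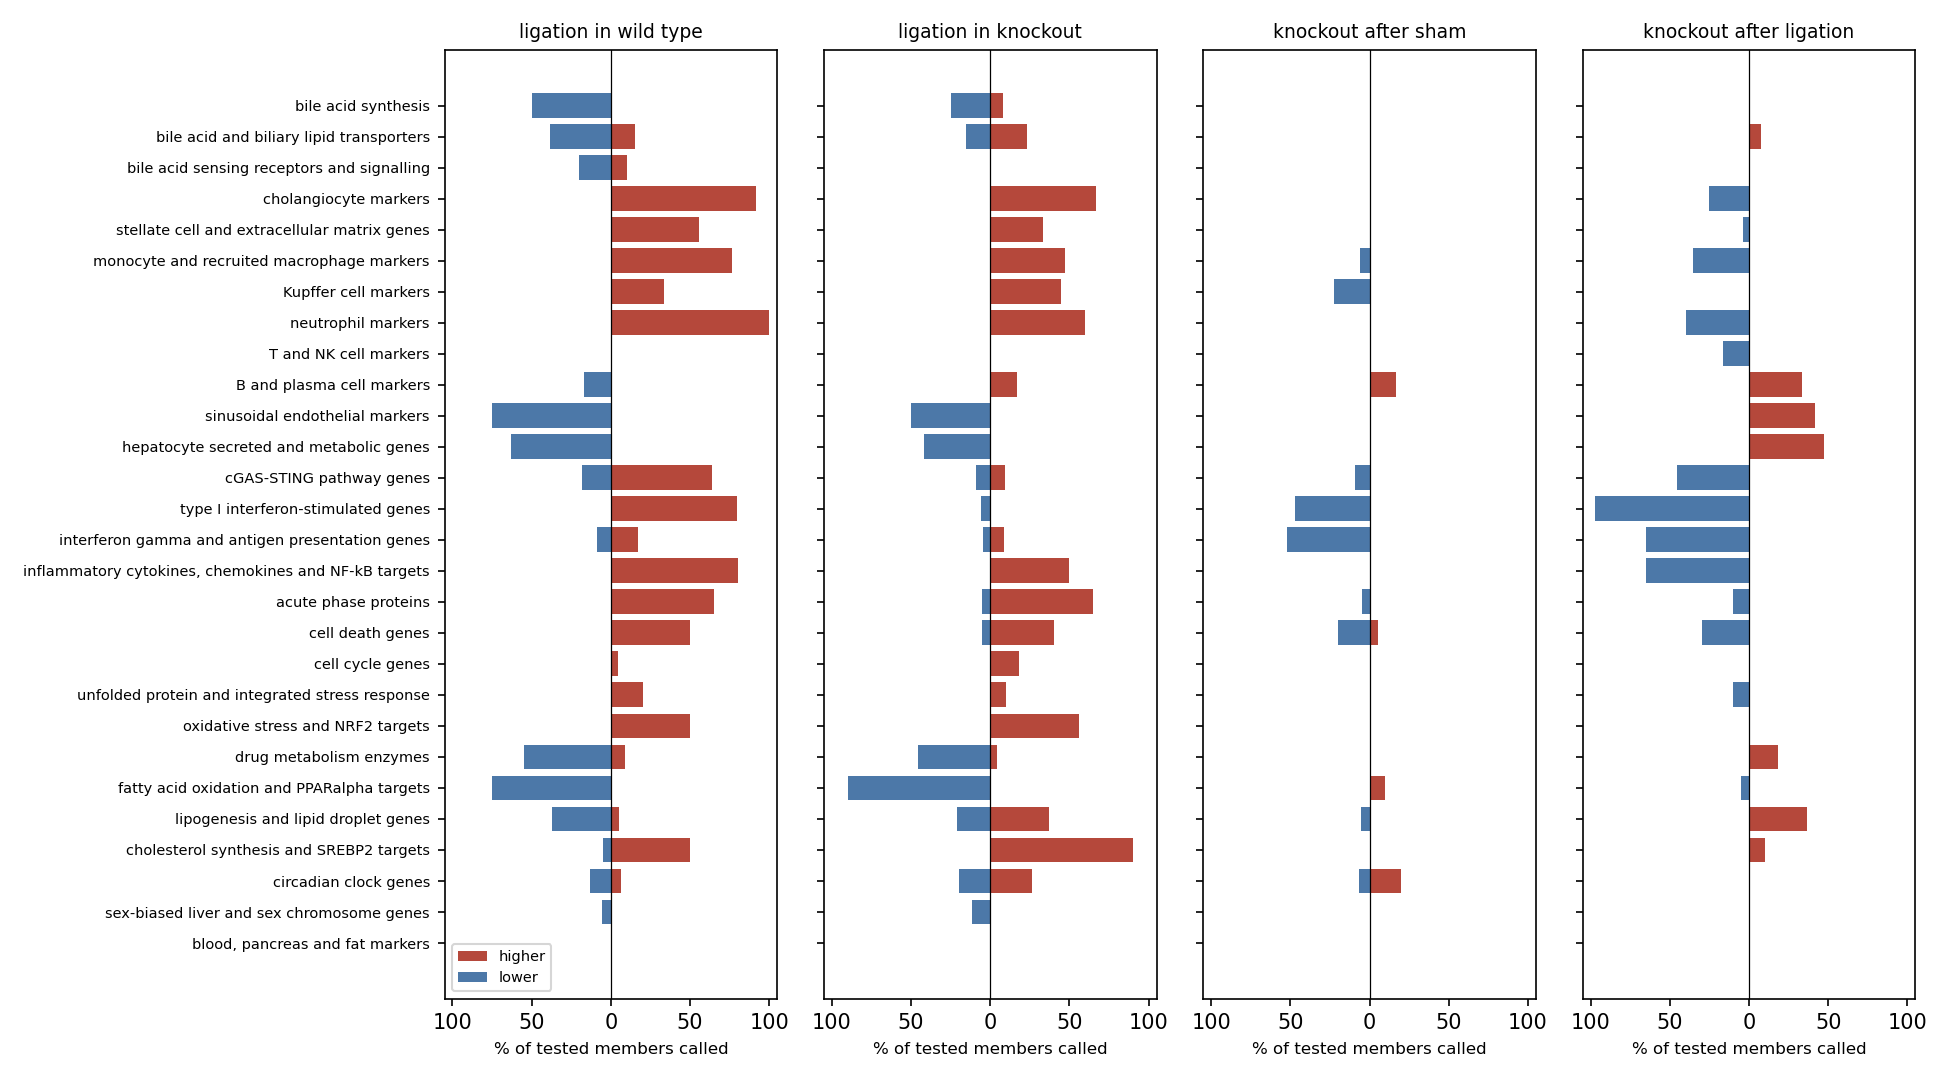
Share of each list's tested members that were called higher (right of 0) or lower (left of 0), in percent, for 28 lists in the 4 pairwise comparisons (limma adjusted p under 0.05). In the panel of knockout after ligation 33 of 34 type I interferon-stimulated genes lie on the lower side, and no list is called by camera with an estimated correlation.

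The third comparison gives the effect of the knockout without cholestasis. Of 34 type I interferon-stimulated genes 16 were lower in sham knockout than in sham wild-type liver, and 4 of 15 clock genes differed. Irf7, a transcription factor of interferon genes, fell by 2.71 ± 0.32, from 59.9 ± 9.99 to 8.80 ± 1.82 FPKM (limma adjusted p = 0.000271). The interferon-inducible GTPase genes Tgtp1 and Irgm2 fell by 2.67 ± 0.45 and 1.22 ± 0.21, and Zbp1, a nucleic acid sensor, fell by 2.16 ± 0.37. Cdkn1a rose by 2.51 ± 0.44, from 2.52 ± 0.646 to 17.4 ± 6.56 FPKM (limma adjusted p = 0.00499). Acot1 rose by 1.89 ± 0.40. The clock repressor gene Nr1d2 fell by 1.70 ± 0.33, while Cry1, another repressor, rose by 1.51 ± 0.35. Cry1 lost its call without any 1 of libraries Sham_Wt_2227, Sham_Wt_2228, Sham_Wt_2229, Sham_KO_2352 and Sham_KO_2353, with an adjusted p of up to 0.0704, and also without a filter, as TPM and in libraries with Y-linked transcripts alone. Tmem173, at -0.80 ± 0.24, did not pass over all genes (limma adjusted p = 0.0779).

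In the sham knockout, 16 of 34 type I interferon-stimulated genes fell, and all 34 adjusted over the list alone, with Ifi44 down by 1.87 and Oasl2 by 1.67 log2 units (log2 fold changes -1.87 ± 0.38 and -1.67 ± 0.31). Of 23 interferon gamma and antigen presentation genes 12 fell, 15 adjusted over the list alone. Camera gave adjusted p = 7.72e-30 and 5.85e-13 for these lists, and adjusted p = 0.37 with an estimated correlation for both. Scaling to total fragments left 8 and 7 members called, with list medians of -1.28 and -0.96. Of 20 cell death genes 4 fell and Cdkn1a rose, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.0219, and 0.0505 without Sham_Wt_2229). Of 20 fatty acid oxidation genes 2 rose, Acot1 among them, and 4 adjusted over the list alone (camera adjusted p = 0.000306). Of 9 Kupffer cell markers 2 fell, 2 adjusted over the list alone, with a list median of -0.23 (camera adjusted p = 0.0292), and with total-fragment scaling none was called, with a median of -0.30. That camera call was lost without library Sham_Wt_2227, Sham_Wt_2228, Sham_KO_2347, Sham_KO_2349 or Sham_KO_2350 (adjusted p = 0.0688, 0.073, 0.0771, 0.0545 and 0.0905) and with library type as a covariate (adjusted p = 0.0608). For the lists of cell death, fatty acid oxidation and Kupffer cells adjusted p = 0.643 with an estimated correlation. No cell cycle gene of 22 passed, nor adjusted over the list alone, while camera ranked the list lower (adjusted p = 0.000426, and adjusted p = 0.714 with an estimated correlation). Of 15 clock genes 3 rose and 1 fell, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.496), and the mean of that list was of opposite sign to the median and the test.

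Camera also called 4 lists in the sham knockout whose members mostly did not pass. None of 20 cytokine and NF-kB target genes was called by limma, nor adjusted over the list alone, and the list ranked lower with a median of -0.37 (camera adjusted p = 0.000306, and adjusted p = 0.643 with an estimated correlation). Of 20 acute phase genes 1 fell, 1 adjusted over the list alone, with a list median of -0.35 (camera adjusted p = 0.0165, 0.203 without Sham_Wt_2229, and adjusted p = 0.732 with an estimated correlation). None of 20 cholesterol synthesis genes passed, nor adjusted over the list alone, with a median of -0.26 (camera adjusted p = 0.0165, 0.0916 without Sham_Wt_2223, 0.104 without Sham_KO_2352, and adjusted p = 0.749 with an estimated correlation). None of 6 blood, pancreas and fat markers passed, nor adjusted over the list alone, 4 of them globin genes, while the list ranked higher with a median of 0.99 (camera adjusted p = 0.0268, and adjusted p = 0.643 with an estimated correlation). That call was lost without Sham_Wt_2227, Sham_Wt_2228, Sham_KO_2347 or Sham_KO_2349 (adjusted p = 0.0687, 0.073, 0.0786 and 0.0637).

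In all, 418 genes differed between the sham groups, 184 higher and 234 lower in the knockout, 104 of them by at least 2-fold. Genes called higher made up 44.0% as deposited, 24.1% after scaling to total fragments (median shift -0.06, 187 genes called) and 10.5% as TPM (median shift -0.12, 190 genes called). The count was 155, 278, 211 and 206 without sham wild-type library Sham_Wt_2227, Sham_Wt_2224, Sham_Wt_2228 or Sham_Wt_2229, 264, 249 and 234 without sham knockout library Sham_KO_2347, Sham_KO_2349 or Sham_KO_2353, and 659 without ligated knockout library BDL_KO_2248, which enters only the estimate of the spread. In libraries with Y-linked transcripts limma called 0 genes, with 1492 at an unadjusted p under 0.05, and in those with Xist 7.

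The comparison named by the series is between ligated livers of both genotypes. In the ligated knockout 33 of 34 type I interferon-stimulated genes, 13 of 20 cytokine and NF-kB target genes and 6 of 17 monocyte markers were lower, and 7 of 19 lipogenesis genes were higher. Ifit1, an interferon-induced RNA-binding protein, fell by 4.25 ± 0.43, from 63.1 ± 34.5 to 2.77 ± 1.64 FPKM (limma adjusted p = 8.39e-06). Isg15, a ubiquitin-like modifier, fell by 3.96 ± 0.48, Rsad2 fell by 3.94 ± 0.49 and Slfn4, a myeloid interferon-stimulated gene, fell by 3.90 ± 0.33. Ly6c2, a surface marker of inflammatory monocytes, fell by 3.21 ± 0.29, from 7.38 ± 4.15 to 0.271 ± 0.192 FPKM, and Tnfaip3 fell by 1.62 ± 0.26. Thrsp, a regulator of lipid synthesis, rose by 3.16 ± 0.53, from 16.5 ± 8.43 to 205 ± 221 FPKM, the desaturase gene Scd1 by 2.14 ± 0.45, the acetyl-CoA carboxylase gene Acacb by 1.82 ± 0.25 and Fasn by 1.36 ± 0.20. Igkc, an immunoglobulin light chain gene of B and plasma cells, rose by 1.68 ± 0.32. It was also higher in sham knockout than in sham wild type, by 1.45 ± 0.32 (limma adjusted p = 0.0203). That sham call was lost in at least 1 removal of a single library.

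**Figure D4:**
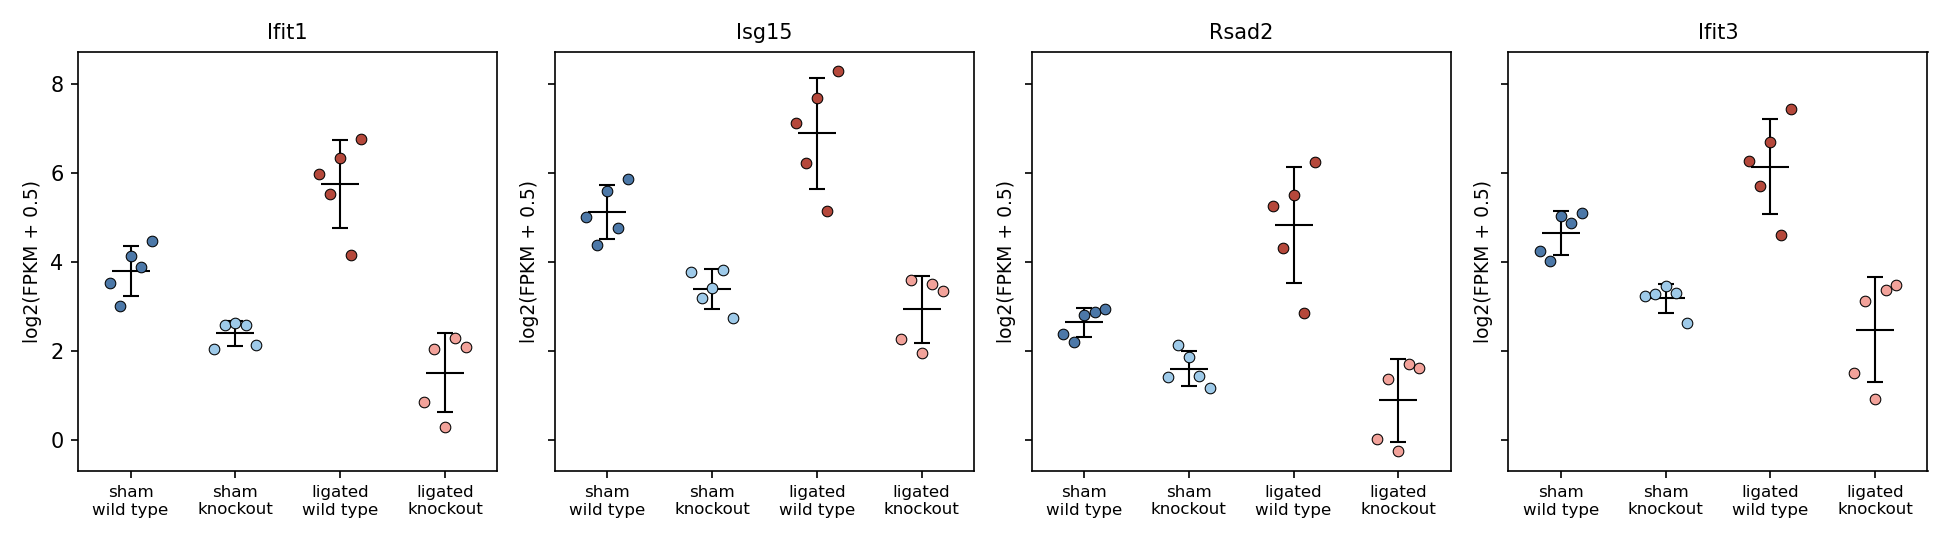
Levels of Ifit1, Isg15, Rsad2 and Ifit3 as log2(FPKM + 0.5) (vertical axis) in the 4 groups (horizontal axis). Each point is 1 liver library and bars are the mean and 1 SD of 5 libraries, and in each panel the 5 ligated knockout points lie below the 5 ligated wild-type points.

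After ligation 33 of 34 type I interferon-stimulated genes were lower in the knockout, and 34 adjusted over the list alone, with a median of -2.50 log2 units (camera adjusted p = 1.71e-52, and adjusted p = 0.0563 with an estimated correlation). Without libraries BDL_KO_2359 and BDL_KO_2248, 33 were called lower, with a median of -1.95. In libraries with Y-linked transcripts alone limma called 32 of them, with a median of -2.70, and in those with Xist it called 0, with a median of -2.41 and, over all genes, 1187 at an unadjusted p under 0.05. Of 23 interferon gamma and antigen presentation genes 15 fell, 15 adjusted over the list alone, with Igtp down to 11.5 ± 2.17 from 88.3 ± 51.5 FPKM, and without the 2 libraries 11 fell, with the list median going from -1.025 to -0.699 (camera adjusted p = 2.64e-17). Of 11 cGAS-STING pathway genes 5 fell, 6 adjusted over the list alone and 5 without the 2 libraries, among them Tmem173 itself and the DNA sensor gene Ifi204, which fell by 2.07 ± 0.22 (camera adjusted p = 6.18e-05). For both of these lists adjusted p = 0.0938 with an estimated correlation.

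Of 20 cytokine and NF-kB target genes 13 were lower in the ligated knockout, 15 adjusted over the list alone (camera adjusted p = 1.42e-11), and of 20 cell death genes 6 were lower, 10 adjusted over the list alone (camera adjusted p = 3.07e-06). For both lists adjusted p = 0.0959 with an estimated correlation, and without libraries BDL_KO_2359 and BDL_KO_2248 each list had 3 members called, with list medians going from -0.93 to -0.60 and from -0.50 to -0.26. The monocyte chemokine gene Ccl2 fell by 2.33 ± 0.57 and lost its call without library BDL_KO_2359, and without both libraries its log2 fold change was -1.22. Of 17 monocyte markers 6 fell, 13 adjusted over the list alone, including Ccr2 (-1.33 ± 0.31, and -0.66 without the 2 libraries), and without them 4 fell and 1 rose, with the list median going from -0.65 to -0.26 (camera adjusted p = 1.31e-08). Of 5 neutrophil markers 2 fell, 3 adjusted over the list alone, and 0 without the 2 libraries, where the list median of -0.78 became -0.58 (camera adjusted p = 0.00543, and 0.0571 without them). For both lists adjusted p = 0.181 with an estimated correlation. Of 12 cholangiocyte markers 3 fell, 5 adjusted over the list alone, and 0 without the 2 libraries, where the list median of -0.78 became -0.14 (camera adjusted p = 0.000607, 0.351 without them, and adjusted p = 0.3 with an estimated correlation). Of 27 stellate cell and matrix genes 1 fell, 1 adjusted over the list alone, namely the growth factor gene Tgfb2, and without the 2 libraries 8 rose and 1 fell, with the list median going from -0.12 to 0.47 (camera adjusted p = 0.182). No Kupffer cell marker of 9 passed, nor adjusted over the list alone or without the 2 libraries (camera adjusted p = 0.0654). Of 6 T and NK cell markers 1 fell, 1 adjusted over the list alone and 0 without the 2 libraries, and of 6 B and plasma cell markers 2 rose, 3 adjusted over the list alone and 2 without the 2 libraries, Igkc and the joining chain gene Jchain (1.22 ± 0.27). Camera gave adjusted p = 0.0369 for both, and adjusted p = 0.431 and 0.361 with an estimated correlation. The T and NK call was lost without BDL_Wt_2237, BDL_Wt_2240, BDL_KO_2359, BDL_KO_2248 or BDL_KO_2370 (adjusted p = 0.0591, 0.115, 0.103, 0.164 and 0.0571) and without both of the 2 libraries (adjusted p = 0.778). The B and plasma call was lost without BDL_Wt_2235, BDL_Wt_2237, BDL_KO_2365, BDL_KO_2370 or BDL_KO_2371 (adjusted p = 0.0641, 0.0649, 0.105, 0.0659 and 0.14) and with library type as a covariate (adjusted p = 0.0595).

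Of 19 lipogenesis and lipid droplet genes 7 were higher in the ligated knockout, and adjusted over the list alone 11 were higher and 2 lower (camera adjusted p = 8.35e-06, and adjusted p = 0.0938 with an estimated correlation). Without libraries BDL_KO_2359 and BDL_KO_2248 9 were higher, and with total-fragment scaling 6. Acss2, which makes acetyl-CoA from acetate, rose by 1.42 ± 0.28. Of 20 cholesterol synthesis genes 2 rose, 6 adjusted over the list alone, and without the 2 libraries 1, where the list median of 0.61 became 0.22 (camera adjusted p = 2.84e-06, and adjusted p = 0.295 with an estimated correlation). Of 19 hepatocyte genes 9 were higher, 15 adjusted over the list alone, among them Ttr (1.11 ± 0.25), and 3 were called without the 2 libraries, where Ttr was not and the list median of 0.77 became 0.39 (camera adjusted p = 1.31e-08). Of 22 drug metabolism enzymes 4 were higher, 4 adjusted over the list alone and 3 without the 2 libraries, including Cyp2c29 (1.47 ± 0.27) (camera adjusted p = 3.83e-05). For these 2 lists adjusted p = 0.181 with an estimated correlation. Of 12 sinusoidal endothelial markers 5 were higher, 7 adjusted over the list alone, such as the lectin gene Clec4g (0.83 ± 0.18), with 10 called without the 2 libraries and 0 with total-fragment scaling, where the list median of 0.51 became 0.33 (camera adjusted p = 6.38e-05, and adjusted p = 0.24 with an estimated correlation).

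In all, 1241 genes differed between the ligated groups, 486 higher and 755 lower in the knockout, 330 of them by at least 2-fold. Genes called higher made up 39.2% as deposited, 11.4% after scaling to total fragments (median shift -0.18) and 7.0% as TPM (median shift -0.25). Without libraries BDL_KO_2359 and BDL_KO_2248 the count was 928, with 49.1% higher, and 522 of these genes were shared with the full set. The count was 618 and 625 without ligated wild-type library BDL_Wt_2236 or BDL_Wt_2233, and 632 and 2061 without ligated knockout library BDL_KO_2359 or BDL_KO_2370. It was 308 in libraries with Y-linked transcripts, 8 in those with Xist and 283 with only these groups in the fit.

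**Figure D5:**
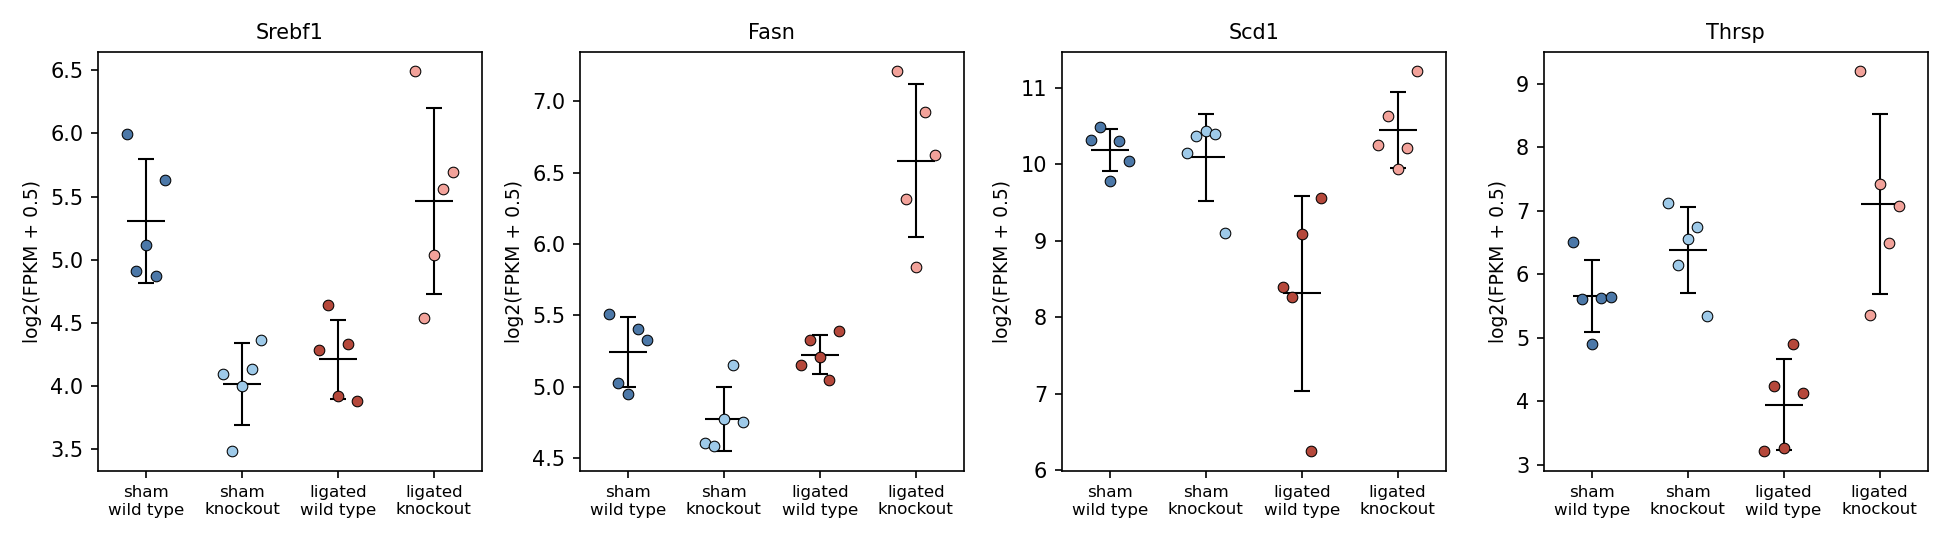
Levels of Srebf1, Fasn, Scd1 and Thrsp as log2(FPKM + 0.5) (vertical axis, with its own range in each panel) in the 4 groups (horizontal axis). Each point is 1 liver library and bars are the mean and 1 SD of 5 libraries, and the 5 ligated knockout points of Fasn lie above the 5 ligated wild-type points.

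The effects of the knockout after sham surgery and after ligation, which share no library, had a Pearson correlation of 0.379 and a Spearman correlation of 0.349 across genes. Among genes called in both, 109 were lower in both and 28 higher in both, where independent lists would share 12.6 and 6.36, and 6 were opposite. Genes near Tmem173 were not called more often than others, with 1 of 104 within 10 Mb against 417 of 13854 elsewhere after sham surgery (Fisher's exact test, two-sided, p = 0.379) and 8 of 104 against 1223 of 13854 after ligation (p = 0.862).

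The last comparison asks which genes respond to ligation differently in the 2 genotypes. Of 19 lipogenesis genes 3 responded more positively in the knockout, and of 34 type I interferon-stimulated genes 3 responded less positively. Srebf1 had an interaction of 2.54 ± 0.42 log2 units (limma adjusted p = 0.0171), measuring 41.0 ± 14.8 and 18.4 ± 4.16 FPKM in sham and ligated wild type but 16.0 ± 3.43 and 48.5 ± 25.7 in the knockout. Fasn and Acaca, which encode fatty acid synthase and acetyl-CoA carboxylase, had interactions of 1.83 ± 0.28 and 1.12 ± 0.17 (limma adjusted p = 0.0119 for both). In the other direction, Serpinb6b, a serine protease inhibitor gene, had an interaction of -3.32 ± 0.61, Cdkn1a of -3.05 ± 0.62, Ifit1 of -2.83 ± 0.61, Slfn4 of -2.38 ± 0.47 and Mx1 of -2.17 ± 0.41. For Cdkn1a the genotypes differed mainly after sham surgery, with 2.52 ± 0.646 FPKM in wild type and 17.4 ± 6.56 in the knockout. Its levels after ligation were 29.1 ± 14.0 and 22.5 ± 17.0. Of 19 lipogenesis genes 3 had a higher interaction, 9 adjusted over the list alone and 5 without libraries BDL_KO_2359 and BDL_KO_2248 (camera adjusted p = 4.49e-07, and adjusted p = 0.12 with an estimated correlation). Of 34 type I interferon-stimulated genes 3 had a lower one, 25 adjusted over the list alone and 2 without the 2 libraries (camera adjusted p = 1.5e-20, and adjusted p = 0.307 with an estimated correlation). No cholesterol synthesis gene of 20 passed, while 9 did adjusted over the list alone and 1 without the 2 libraries (camera adjusted p = 4.38e-11, and adjusted p = 0.307 with an estimated correlation).

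Limma called 53 genes with an interaction, 22 higher and 31 lower. Genes called higher made up 41.5% as deposited, 38.1% after scaling to total fragments (median shift -0.11, 21 genes called) and 55.6% as TPM (median shift -0.13, 9 genes called), and 178 genes, 63.5% of them higher, were called without libraries BDL_KO_2359 and BDL_KO_2248. The count was 17, 19, 15, 13 and 13 without sham wild-type library Sham_Wt_2223, Sham_Wt_2224, Sham_Wt_2227, Sham_Wt_2228 or Sham_Wt_2229, and 18, 9, 10 and 16 without sham knockout library Sham_KO_2349, Sham_KO_2350, Sham_KO_2352 or Sham_KO_2353. It was 9, 8, 112 and 26 without ligated wild-type library BDL_Wt_2233, BDL_Wt_2236, BDL_Wt_2237 or BDL_Wt_2240, and 21, 86, 151 and 15 without ligated knockout library BDL_KO_2359, BDL_KO_2365, BDL_KO_2370 or BDL_KO_2371. Of the 15 named genes with an interaction, Srebf1, Fasn and Acaca were called in all 20 of these fits. That does not extend to every other setting, since in libraries with Xist alone limma called 0 genes (793 at an unadjusted p under 0.05). Nor does removal of single libraries test a difference shared by a whole group. The sham difference of Srebf1, knockout against wild type, was -1.29 ± 0.29 log2 units (limma adjusted p = 0.0229) and enters its interaction. Clock genes also differed between these sham groups. Over the 6471 genes called for the average ligation effect, the mean response per library was 0.73 log2 units in wild type and 0.58 in the knockout, 78.6% of it. That difference, -0.16, was within the range that exchange of genotype within each surgery gives (exact permutation, two-sided, p = 0.223). A genotype difference shared by both surgeries widens that range. Without libraries BDL_KO_2359 and BDL_KO_2248, with the genes of the score chosen again, the difference was -0.02 (exact permutation p = 0.825). The test covers the difference of responses only, not the scores themselves. With all libraries, every knockout score lay below every wild-type score of the same surgery. The highest knockout and lowest wild-type scores were 0.668 and 0.674 after ligation, and -0.076 and -0.049 after sham surgery.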

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

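All tests but that of the feeding state, namely those on the number of macrophages and monocytes, on the 2 libraries that stand apart, on library scaling, on label swaps, on tissue composition and on the clock, and the counts of regroupings, were chosen only after the result was seen.

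Over 95 genes, the response score, the assigned fragments and the total FPKM, 22 of 392 groups of 5 libraries tested (5.6%) held 1 library that lay far from the other 4, and chance gives about 1 in 20. In sham wild type these were Acacb at 20.52 FPKM in Sham_Wt_2228, Epcam at 1.05 in Sham_Wt_2224, and Cyp8b1 at 43.4, Irf9 at 17.2, Prtn3 at 12.6 and Rtp4 at 28.8 in Sham_Wt_2229. In sham knockout they were Acss2 at 13.2, Ifit3 at 5.74 and Scd1 at 548 in Sham_KO_2353, Hpd at 786 and Retnlg at 0.761 in Sham_KO_2350, and Irf9 at 8.01 in Sham_KO_2349. In ligated wild type they were Acacb at 5.61 in BDL_Wt_2240, Clec4g at 3.92 and Irf9 at 12.1 in BDL_Wt_2237, and Mup15 at 8.98 and Nsdhl at 33.8 in BDL_Wt_2235. In ligated knockout they were Hsd3b5 at 0.301 in BDL_KO_2359, and Mup12 at 1.28, Mup15 at 0.408, Mup16 at 3.79 and Orm2 at 349.9 in BDL_KO_2365.

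The response to ligation differed between genotypes for 53 genes by the interaction test. Among the genes named by the rule, the interaction in log2 units was 2.54 for Srebf1, 1.83 for Fasn, 1.75 for Ripply1, 1.60 for 1700001C19Rik, 1.39 for Cabcoco1, 1.12 for Acaca, -3.32 for Serpinb6b, -3.05 for Cdkn1a, -2.83 for Ifit1, -2.38 for Slfn4, -2.17 for Mx1, -1.99 for Ly6c2, -1.78 for Tnfaip3, -0.82 for Irf9 and -0.57 for Bid. All but Srebf1, Fasn and Acaca lost their call in at least 1 removal of a single library.

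Interferon-stimulated genes were lower in ligated knockout livers, with a list median of -2.50 log2 units. Against a smaller number of macrophages and monocytes as the whole cause, the median of their 26 markers was -0.65, with median absolute deviations of 0.314 for the markers and 0.869 for the interferon-stimulated genes. The 17 monocyte markers alone had a median of -0.65, but among them Ly6c2, a marker of inflammatory monocytes, fell by 3.21 ± 0.29. The scale also understates changes of low genes, so these medians cannot exclude a loss of inflammatory monocytes alone. A factor per library moves all genes alike, and against it as the cause the list median lay at -2.51 from the median of all 14059 genes, with median absolute deviations of 0.869 and 0.273, while against the 2 libraries that stand apart, 33 were called without them. The loss of STING may lower these genes, as a hypothesis found and tested on the same data, and a change in the state of the cells or of another cell type was not tested. Nor was a difference between the series of library numbers, which nearly follow genotype.

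Ligated knockout libraries BDL_KO_2359 and BDL_KO_2248 lay apart from the other 3, and the number of BDL_KO_2248 lies outside the series of the other knockout libraries, Sham_KO_2347 to BDL_KO_2371, and of wild type, Sham_Wt_2223 to BDL_Wt_2240. Apart from BDL_KO_2248, genotype thus follows the series of numbers, whose meaning is not given in the sources used here. If the numbers mark cohorts or sampling days, a difference between these cannot be told apart from the knockout. A swap of surgery labels with sham knockout libraries would need a partner out of place, but the highest response score of a sham knockout library was -0.076, below the lowest ligated knockout score of 0.265. The genes of that score were chosen with the surgery labels, which limits this check. On the first principal component, whose values use no labels, the highest sham knockout library lay at -33.3 and the lowest ligated knockout library at -0.403. A swap with ligated wild-type libraries would bring their Tmem173 level, but the higher of the 2 was 0.840 FPKM against a lowest ligated wild-type value of 2.60. However, Tmem173 averaged 1.71 FPKM in sham and 3.64 in ligated wild type, and Sham_Wt_2224 measured 0.843. A wild-type liver with a weaker response to ligation could thus reach such a level, so it cannot exclude this swap. Pieces of tissue richer in hepatocytes could account for the values, since all 6 lists of other cells lay below the range of the other 3 libraries in both. Most of these lists rose with ligation in wild type, however, so a weaker response would lower them too. Sinusoidal endothelial markers, which fell with ligation, were also low, at 2.13 in BDL_KO_2248 and 1.84 in BDL_KO_2359, against 2.61 to 3.05 in sham knockout. Hepatocyte genes of both libraries, at 10.38 and 10.41, lay within the sham knockout range of 10.17 to 10.50. The response scores of BDL_KO_2359 and BDL_KO_2248, 0.265 and 0.391, were the lowest of the group, with 0.401 in BDL_KO_2371, so a weaker response of these livers to ligation stays open as well.

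Of 15 clock genes 4 were called between the sham groups, while camera, which takes no account of phase, did not call the list (adjusted p = 0.496). A score of 2 genes minus 6 genes of opposite phase, all among those not called, was 1.94 log2 units higher in the sham knockout, with SDs of 0.756 in wild type and 0.202 in knockout livers. The values had been seen when the score was set, and the sampling times are not given in the sources used here, so another time of day cannot be told apart from an effect of the genotype on the clock. In ligated livers the score differed by -0.33, with SDs of 1.89 and 1.21, which leaves both open. A fasting score differed by 0.24 (exact permutation p = 0.532), less than its spread between livers, so another feeding state cannot be told apart from none.

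Each count of genes was set against 100 splits of the same libraries, the real one included. As many genes were called in 1 split, the real one, for ligation in wild type (5011, highest other 73), for ligation in the knockout (3534, highest other 1136), for the knockout after sham surgery (418, highest other 3) and for the knockout after ligation (1241, highest other 1036, in a split that only exchanges BDL_Wt_2237 and BDL_KO_2365). For these 4 counts 1 of 100 is the smallest share the splits can give, so a random grouping rarely gives counts as large. The splits do not test the size of a count. For the interaction 3 of 100 splits gave as many, with 53 in the real one and 256 in the highest other, several times the real count, which points to a structure of the samples. That split parts the sham libraries by Y-linked transcripts and Xist and groups 4 of the 5 ligated libraries with Y-linked transcripts, and with library type as a covariate the real split gave 52 genes, 44 of them among the 53.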

How the results depend on the processing

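Total-fragment scaling, voom, the library type covariate, each library type alone and removal of libraries BDL_KO_2248 and BDL_KO_2359 were chosen only after the data were seen. For the named genes, all alternatives but the pseudocounts, median-ratio scaling and removal of single libraries were added after the data were seen, and in none of them did a called named gene reverse its direction. The balance of calls crossed 50% for ligation in the knockout (48.8% higher, 57.8% with total-fragment scaling and 77.0% as TPM), for ligation in wild type (50.8%, and 48.3% with a filter at 1 FPKM) and for the interaction (41.5%, 55.6% as TPM and 63.5% without the 2 libraries), among other settings. In the interaction the stellate cell and matrix list, called lower by camera with a median of -0.29, was called higher without the 2 libraries, with a median of 0.39. Camera called 16 lists in the interaction with all libraries and 12 without the 2, with 7 shared in direction. The lists of cholangiocyte, monocyte, hepatocyte, cGAS-STING, interferon gamma, cytokine, cell death and drug metabolism genes lost their call there. Genes changed by ligation in wild type were 3126 with only Y-linked libraries and 911 with only Xist libraries, where fewer libraries entered. For ligation in the knockout the counts were 1072 and 550, and 1694 with only the 2 groups in the fit. For the knockout after sham surgery they were 0 by limma (1492 at an unadjusted p under 0.05) and 7, 208 without a filter, 190 as TPM, 1234 with array weights, 187 with total-fragment scaling, 1041 without the 2 libraries and 821 with only the 2 groups. For the knockout after ligation they were 308, 8 and, with only the 2 groups, 283. For the interaction they were 2 and 0 by limma (793 at an unadjusted p under 0.05), 9 without a filter, 9 as TPM, 142 with array weights, 21 with total-fragment scaling, 178 without the 2 libraries and 23 with voom. With only the 2 groups in the fit, counts rose where no ligated knockout library entered (5011 to 6209 and 418 to 821). They fell where these libraries entered (3534 to 1694 and 1241 to 283), so fewer groups alone do not account for these falls. The full fit shares 1 estimate of the spread. The SD of the response score was 0.157 in ligated knockout livers against 0.039 to 0.0623 in the other groups. Standard errors of comparisons with that group may thus be too small. For the other settings, apart from the smaller number of libraries, the cause was not tested. With an estimated correlation camera called 0 lists in each of the 5 comparisons, against 17, 15, 10, 17 and 16. Leaving out each library in turn gave 4279 to 5466 and 2614 to 4096 genes for ligation in wild type and in the knockout, 155 (without Sham_Wt_2227) to 659 (without BDL_KO_2248) for the knockout after sham surgery, 618 (without BDL_Wt_2236) to 2061 (without BDL_KO_2370) after ligation and 8 (without BDL_Wt_2236) to 151 (without BDL_KO_2370) for the interaction, with the other libraries that moved a count by over 1.5 times given in the report. Tmem173 ranged from -0.97 to -0.70 log2 units in sham and from -1.37 to -1.01 in ligated livers. Of 141 results for named genes, 11 lost their call with a pseudocount of 0.1, 2 with 1, 14 without the 2 libraries, 6 with the covariate, 19 with total-fragment scaling 28 with voom, 28 without a filter, 27 as TPM, 3 with quantile normalization, 8 with array weights, 67 and 101 with only Y-linked or only Xist libraries and 23 of 126 with only the 2 groups, and 314 of 2820 were lost over the removals of single libraries, with none reversed. Median-ratio scaling tests nothing here, since the deposited values already carry it. Depth limits genes with few fragments.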

Other observations

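The comparison of cell cycle genes without libraries BDL_KO_2248 and BDL_KO_2359 was chosen only after the result was seen. With all libraries 4 of 22 cell cycle genes rose with ligation in the knockout and limma called 0 of them between ligated knockout and wild type (over all genes, 3459 at an unadjusted p under 0.05), but without those 2 libraries 21 rose with ligation, with a list median of 1.99, and 12 were higher than in ligated wild type, with a median of 1.07. With all libraries camera already called the list higher for ligation in the knockout, with a median of 1.05 (camera adjusted p = 1.34e-05, and adjusted p = 0.459 with an estimated correlation). It also called the list higher in the interaction, with a median of 0.78 (camera adjusted p = 6.99e-05, and adjusted p = 0.535 with an estimated correlation). The lower levels in sham knockout than in sham wild type, with a list median of -0.61, enter both. Mcm6, a subunit of the replicative helicase, measured 1.46, 5.28, 0.960, 8.99 and 20.98 FPKM in BDL_KO_2359, BDL_KO_2365, BDL_KO_2248, BDL_KO_2370 and BDL_KO_2371, against 2.93 to 4.78 in ligated wild type. Birc5, which acts in cell division, measured 0.431, 2.77, 0.604, 0.950 and 4.87 FPKM in the same libraries, against 0.484 to 0.933 in ligated wild type.

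Mup12 and Hsd3b5, 2 male-biased genes chosen after their values were seen, differed with the library type in sham livers, while the list of 17 sex-biased genes was not called for ligation in either genotype (camera adjusted p = 0.198 and 0.312). Mup12 measured 1493 to 3452 FPKM in the 5 sham libraries with Y-linked transcripts, 2.74 to 158 in the 5 sham libraries with Xist, and at most 1.28 in the 10 ligated libraries. Hsd3b5, a steroid-metabolizing enzyme gene, measured 115 to 207, 0.984 to 20.6 and at most 0.301 FPKM in the same sets of libraries. The library types were read from the data, and neither they nor the sex of the animals is a group of the study.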
